A study of Mus musculus with 7 samples.

How the data were processed

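RNA sequencing was compared between 4 wild-type libraries (Calr +/+ MxCre) and 3 libraries of the mutant genotype (labelled Calr fl/fl (Calr del52/del52) MxCre) of sorted mouse long-term haematopoietic stem cells. MxCre is a Cre recombinase switched on by interferon, and pI:pC, a double-stranded RNA mimic, was given to all mice to induce it. Cells were collected by their surface markers (CD150 on, CD48 off, Sca-1 and Kit on, lineage markers off) 14 days after induction began, and no drug was given, per the labels' protocols. RNA was isolated with a PicoPure kit, amplified as cDNA with SMART-Seq v4, sheared and made into libraries with the Swift 2S Plus kit, per the labels' protocols. The libraries were unstranded, per the labels. Reads from overlapping or antisense genes, such as Plxna4os1 and its partner Plxna4, therefore cannot be told apart, and near-identical copies such as Hspa1a and Hspa1b may have shared reads.

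FastQC 0.11.7, STAR 2.7.3a, HTSeq 0.6.1, Cufflinks 2.2.1 and DESeq2 1.12.4 were the tools of the authors and GRCm38 the genome build, per the submitters' processing notes. The options of each tool and the removal of low genes are not given in the sources used here. The gene signal deposited by the authors was a normalized count, 1 column per library, for 19649 genes. In each library 100% of the values were whole multiples of a single step, within a tolerance of 0.01 reads, so whole read counts and 1 size factor per library were recovered. Every gene in the table had reads in at least 4 libraries. The second deposited table gave FPKM (fragments scaled by transcript length and library size) estimated by the authors for 66660 transcripts. Positions and exonic lengths came from the GENCODE vM21 annotation of GRCm38, which matched 19382 genes (98.6%) and 66303 transcripts (99.5%).

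The comparison was mutant minus wild-type over all 7 libraries. Genes with a normalized count of at least 10 in at least 3 libraries (16047 genes) were tested with limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with a variance trend and no covariate. Tests were two-sided, and the threshold was a Benjamini-Hochberg adjusted p of 0.05. The level of Calr was compared by an exact permutation test over the 35 splits of the libraries into 4 and 3, whose smallest possible p is 0.0286. Transcripts with an FPKM of at least 1 in at least 3 libraries (30156 transcripts) were tested with limma on log2(FPKM + 1). Log2 differences are differences of group means of log2 values, SE is limma's standard error, and means are followed by the SD over 4 wild-type or 3 mutant libraries.

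Gene lists were fixed for protein folding, the proteasome, signalling, blood lineages, the cell cycle, stress and metabolism, with 1147 memberships, of which 1089 were in the table and 4 were matched through another symbol. A total of 36 lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01. The same lists were also tested with a correlation estimated per list, with limma's fry rotation test, and against 10000 random lists matched on exonic length and expression. A list of sex-linked genes was kept for a technical check and not tested, and 0 of its Y-linked genes were in the table. Genes to be named were Calr, the 12 largest changes in each direction among genes that passed or, where fewer than 5 passed, the 5 genes of smallest p, the 4 leading members of each called list, the 3 leading members of 10 lists chosen by topic, and 14 genes of the pathways studied. Some genes that the rule names are not reported here. The rule named 83 genes, of which 78 had the same sign in every alternative set out beforehand. These tests, lists, naming rules and a first set of alternatives were written before the data were examined.

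That first set changed the pseudocount, the filter, the scaling (TMM or quantile), library weights, the variance model, the test (edgeR 4.0.16 or DESeq2 1.42.0 on recovered reads), the table used and the libraries, each left out in turn. The library weights were 11.2 for mutant 1 and 0.42 to 1.05 for the other libraries, so fits with them rest mostly on mutant 1 for the mutant group. A further set was chosen after seeing the data, because wild-type 3 and 4 stood apart from wild-type 1 and 2. It left out either wild-type pair, kept only the libraries outside the title series shared by both groups, added the slope of each library's deviations against log exonic length as a covariate, or added the series of numbers in the sample titles as a covariate. Wild-type 3 and 4 and mutant 1 and 2 carry title numbers of one series, and the other titles do not. Whether this series marks a batch is not given in the sources used here. No number is shared between the groups, so no pairing was fitted.

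The fits were tested on simulated reads for the same 16047 genes, with 200 genes changed and libraries of the same size. Every simulated gene had the same preset spread between libraries, which was not estimated from these data. The changed genes were drawn from those with higher counts, and other spreads were not simulated. With no split within the wild-type group, limma called 100% of genes changed 2-fold. With the split between the wild-type pairs carried into the simulation, limma called 8% of genes changed 2-fold and 74% of genes changed 4-fold. The fit with the length slope then called 94% and 100%, and the fit without wild-type 3 and 4 called 90% and 100%. The simulations varied only whether that split was carried, and these fits absorb it or leave it out. Their high shares therefore follow in part from the design. The real mutant libraries also differed in length slope (0.04 in mutant 2, -0.58 in mutant 3). Whether these shares hold for the real libraries was not tested. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 made the tables and plots.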

Results

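Long-term haematopoietic stem cells, which renew the blood system, were profiled in 4 wild-type and 3 Calr del52/del52 libraries. Calreticulin, the product of Calr, is a calcium-binding chaperone of the endoplasmic reticulum (ER). The del52 allele replaces its C terminus, and mutants of this kind occur in myeloproliferative neoplasms. The reads counted in wild-type 1 to 4 were 22555594, 22990781, 28710304 and 28537617, and those in mutant 1 to 3 were 21618204, 27083569 and 21325340. Between 19189 and 19347 of 19649 genes had reads in a given library. Mitochondrial genes took 0.363% to 0.711% of reads in the wild-type and 0.683% to 1.17% in the mutant libraries. The labels do not state that each library came from a separate animal, so p-values measure only the spread between these libraries.

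The wild-type libraries formed a pair of pairs. Wild-type 3 and 4 were far from the other 5 libraries on the first principal component, which held 55.9% of the variance. Pearson's r of log2 values over genes, which are not independent replicates, was 0.982 between wild-type 1 and 2, 0.984 between wild-type 3 and 4, and 0.930 between wild-type 1 and 3. Kit, the stem cell factor receptor on which the cells were sorted, had 4150 and 4068 normalized counts in wild-type 1 and 2 but 26511 and 25305 in wild-type 3 and 4. The mutant libraries had 4736, 6677 and 2976. Between these wild-type pairs, 8810 of 16047 genes differed with limma, 4749 higher and 4061 lower in wild-type 3 and 4. The difference followed exonic length across genes (Spearman's rho 0.51 over 15901 genes), so long transcripts were higher and short ones lower in wild-type 3 and 4.

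**Figure D1:**
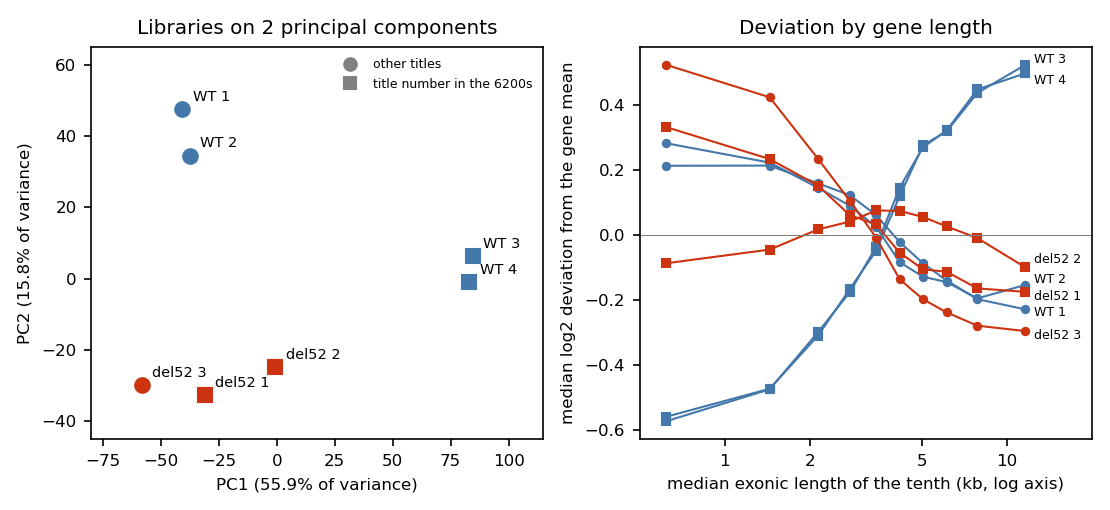
The left panel places the 7 libraries on the first and second principal components (% of variance on the axes), wild-type in blue and Calr del52/del52 in red, with squares for titles numbered in one series and circles for the others. The right panel gives each library's median log2 deviation from the gene mean against median exonic length (kb, log axis) for genes grouped by length, and only wild-type 3 and 4 climb from the shortest to the longest genes.

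The first question was whether the edited gene kept its level. Calr (ENSMUSG00000003814.8, chromosome 8, 84841850 to 84846934, GRCm38) had 18606, 16639, 15922 and 15965 normalized counts in wild-type 1 to 4 and 14239, 15724 and 15317 in mutant 1 to 3. The means were 16783 ± 1259 (SD, n = 4) and 15093 ± 767 (SD, n = 3). Every mutant library was below every wild-type library, but the log2 difference of -0.15 did not pass the exact permutation test (two-sided p = 0.0857). Summed over the transcripts of Calr, FPKM gave a log2 difference of -0.13 and an exact p of 0.0286, the smallest these splits allow. The allele changes the coding sequence and need not change the transcript level, so these values check the labels only weakly.

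The second question, taken from the title of the series, was how ER stress and protein folding genes stood in the mutant cells. The list of ER chaperones and folding enzymes rose, with 24 of 31 members above the wild-type mean and a median log2 difference of 0.41 (camera, adjusted p = 7.05e-05). With an estimated correlation the call was lost (adjusted p = 0.591), while the call at the preset correlation held with any 1 library left out. The median was 0.26 with the length slope as a covariate and 0.25 without wild-type 3 and 4. An exact permutation of the list's mean, added after seeing the data, gave p = 0.0286, the smallest these splits allow, which could not pass an adjustment over 36 lists unless many of them reached it. The list averaged -0.07, -0.11, -0.33 and -0.08 in wild-type 1 to 4 and 0.14, 0.17 and 0.28 in mutant 1 to 3, as log2 deviations from the gene means. Its members included Pdia3, the disulfide isomerase that works with calreticulin on glycoproteins, at 22272 ± 6407 (n = 4) and 38055 ± 4525 (n = 3) normalized counts (log2 0.82, SE 0.27). Pdia4, another disulfide isomerase, had 5593 ± 1304 and 8900 ± 329 (log2 0.70, SE 0.21). Hsp90b1, the ER form of HSP90, had a log2 difference of 0.63 (SE 0.22), and Sil1, the exchange factor of the chaperone BiP, 0.58 (SE 0.15). All of these had every mutant library above every wild-type library. Hspa5, which encodes BiP, had 31132 ± 5293 and 38288 ± 4882 normalized counts, with overlapping groups (log2 0.31, SE 0.20).

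No single gene passed limma's test over all 7 libraries. Limma called 0 of 16047 genes (smallest adjusted p 0.538), with 1365 at an unadjusted p under 0.05; edgeR called 0, with 1637 unadjusted, and DESeq2 called 84 (34 higher, 50 lower). All other single-gene values are measured differences that did not pass limma's test over all 7 libraries. Groups did not overlap in 1536 genes (9.57%, against 5.71% by chance), 840 higher and 696 lower in the mutant. With the length slope as a covariate, limma called 126 genes (98 higher, 28 lower), and without wild-type 3 and 4 it called 51 (38 higher, 13 lower). A total of 29 genes were called in both of these fits, all with the same sign, but both fits were chosen after seeing the data. The slope was 0.81 in wild-type 3 and in wild-type 4, against -0.58 to 0.04 in the other libraries. Both fits therefore set that pair apart, so their agreement is not separate support. With the title series as a covariate limma called 3597 (1599 higher, 1998 lower), and with slope and series together 0 (1071 unadjusted). Within the title series shared by wild-type 3 and 4 and mutant 1 and 2, limma called 6010 genes (2631 higher, 3379 lower). Outside it, where mutant 3 stands alone and is assumed to vary like the wild-type libraries, it called 1022 (554 higher, 468 lower).

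Genes that sense and relay ER stress had mixed values. Xbp1, the transcription factor spliced by IRE1, had 5566 ± 540 normalized counts in wild-type (n = 4) and 9239 ± 1480 in mutant libraries (n = 3), a log2 difference of 0.72 (SE 0.17). It was called by DESeq2 (adjusted p = 0.0464) and was the 1 member of the list of unfolded protein response sensors and transducers to pass in limma when adjusted over the list alone. Ddit3, which encodes the pro-apoptotic factor CHOP, had 723 ± 156 and 1166 ± 51.7 (log2 0.72, SE 0.22), and Atf4 had a log2 difference of 0.20 (SE 0.17). Atf6b, a paralogue of the sensor ATF6, had a log2 difference of -0.53. It had -0.23 without wild-type 3 and 4 and -0.84 without wild-type 1 and 2. That list was not called over all libraries (14 members, median 0.10 but mean -0.06, adjusted p = 0.723). It rose without wild-type 3 and 4 (adjusted p = 1.97e-03), where no list passed with an estimated correlation. The ATF4 and CHOP targets were not called either (33 members, median 0.03, adjusted p = 0.717), with log2 differences of 0.75 for Trib3, 0.92 for Nupr1 and -1.14 for the amino acid transporter Slc7a5. Slc7a5 had -0.46 without wild-type 3 and 4 and -1.82 without wild-type 1 and 2. ER-associated degradation, which feeds misfolded proteins to the proteasome, had a median of 0.00 over 32 members (camera, adjusted p = 0.695). Derl3, Selenos and Selenok had 1.54, 0.81 and 0.65. They had 1.57, 0.42 and 0.37 without wild-type 3 and 4, and 1.51, 1.21 and 0.92 without wild-type 1 and 2. N-glycosylation had a median of 0.07 over 47 members (camera, adjusted p = 0.324). Rpn1, Uggt1 and Mogs had 0.44, -0.66 and -0.49. They had 0.31, -0.22 and -0.27 without wild-type 3 and 4, and 0.57, -1.10 and -0.71 without wild-type 1 and 2. ER translocation and vesicle transport (0.12, adjusted p = 0.0974), calcium handling in the ER (-0.20, adjusted p = 0.724) and the cytosolic heat shock response (0.14, adjusted p = 0.136) did not pass.

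**Figure D2:**
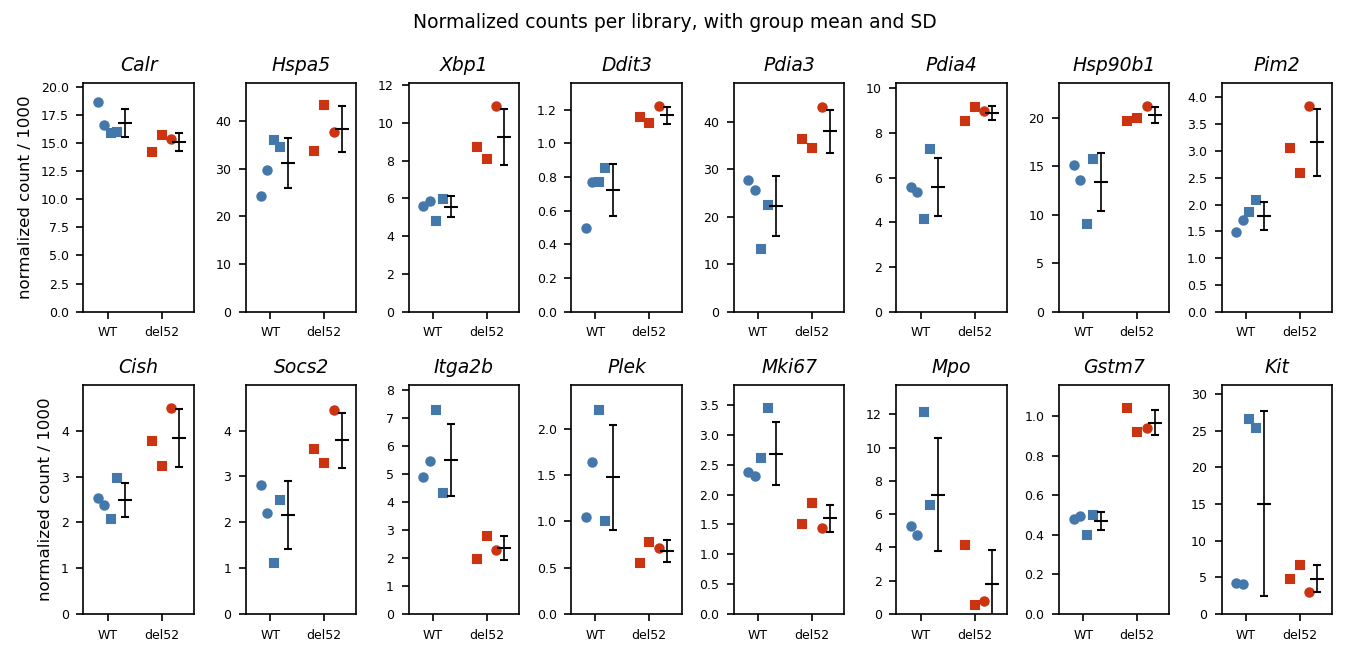
Normalized counts (divided by 1000, axes from 0) of 16 genes, 1 point per library, wild-type in blue and Calr del52/del52 in red, squares and circles as in the plot of libraries, with black bars for the group mean ± SD (n = 4 and 3). Xbp1, Ddit3, Pdia3, Pdia4, Hsp90b1, Pim2, Cish, Socs2 and Gstm7 have every mutant library above every wild-type library, and Calr, Itga2b, Plek, Mki67 and Mpo every one below.

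The proteasome, the other target named in the title, gave a result that turned with the choice of wild-type libraries. Over all 7 libraries the list of proteasome genes rose (38 of 44 members positive, median log2 0.33, camera adjusted p = 2.9e-03). With an estimated correlation the camera adjusted p was 0.853. Psmb1 and Psma1 of the core particle had log2 differences of 0.56 and 0.45. Psmd10 and the regulatory subunit Sem1 had 0.50 and 0.62, and the activator Psme4 had -0.48. Psmb1 had 10177 and 9670 normalized counts in wild-type 1 and 2, 4630 and 4571 in wild-type 3 and 4, and 9577, 8064 and 12898 in the mutant libraries. Psma1 and Sem1 had -0.04 and -0.01 without wild-type 3 and 4. Without wild-type 3 and 4 the list was lower in the mutant (median -0.16, adjusted p = 6.8e-04; 0.782 with an estimated correlation), and with only wild-type 3 or only wild-type 4 left out it was not called (adjusted p = 0.0930 and 0.109). The immunoproteasome and MHC class I list was not called (median 0.15, adjusted p = 0.841), and it was lower without wild-type 3 and 4 (median -0.21, adjusted p = 0.0069; 0.552 with an estimated correlation).

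Oxidative phosphorylation and the cytosolic ribosome, whose genes are short, followed the same libraries. All 79 ribosomal protein genes had positive differences (median 0.76), and the list rose (camera, adjusted p = 2.5e-22; adjusted p = 0.843 with an estimated correlation). Rpl10, Rpl3, Rps27 and Rps3a1 had log2 differences of 0.83, 0.56, 0.93 and 0.79. Oxidative phosphorylation rose with 73 of 75 members positive (median 0.55, adjusted p = 2.3e-09; adjusted p = 0.853 with an estimated correlation). The complex I subunits Ndufb11, Ndufa6 and Ndufc2 had 0.62, 0.74 and 0.66, and Uqcrh of complex III had 0.70. Without wild-type 3 and 4 the ribosomal median was 0.23 (adjusted p = 1.06e-05; 0.825 with an estimated correlation), and that of oxidative phosphorylation was -0.08 (adjusted p = 0.0456, lower in the mutant; 0.905 with an estimated correlation).

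Genes of JAK2 and STAT5 signalling, which is active in myeloproliferative neoplasms, were compared next. Pim2, Cish and Socs2, kinase and feedback genes induced by STAT5, had log2 differences of 0.82 (SE 0.20), 0.62 (SE 0.19) and 0.89 (SE 0.32), with every mutant library above every wild-type library. Pim2 had 1784 ± 255 (n = 4) and 3163 ± 626 (n = 3) normalized counts and was called with the length slope (limma, adjusted p = 0.0443). The list of STAT5 targets was not called (19 members, median -0.10 but mean 0.10 and test upward, adjusted p = 0.723). It rose without wild-type 3 and 4 (adjusted p = 3.4e-03), where no list passed with an estimated correlation. Jak2 and Stat5a themselves had -0.76 and -0.57, and Jak2 ranged from 901 to 3073 normalized counts within the wild-type group. Without wild-type 3 and 4 they had 0.10 and 0.08, and without wild-type 1 and 2 -1.62 and -1.22, so their direction came from wild-type 3 and 4. The MAPK output list was not called over all libraries (median -0.41, adjusted p = 0.102). It was lower without mutant 2 (adjusted p = 0.0316), with library weights (0.0485), within the shared title series (0.0313) and without wild-type 1 and 2 (0.0241). The test pointed upward without wild-type 3 and 4 (median 0.20, adjusted p = 0.399) and with the length slope (median 0.19, adjusted p = 0.165), and with an estimated correlation over all libraries the adjusted p was 0.853.

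By its mean in each library, the stem cell marker list was higher in the mutant than in wild-type 1 and 2 but not than in wild-type 3 and 4. The difference between these comparisons was not tested, and no list passed without wild-type 3 and 4 when the correlation was estimated. The stem cell marker list averaged -0.27, -0.17, 0.11 and 0.11 in wild-type 1 to 4 and 0.11, 0.01 and 0.11 in mutant 1 to 3, as log2 deviations from the gene means. Over all libraries the list of haematopoietic stem cell markers rose (23 of 36 positive, median 0.25, camera adjusted p = 0.0463; adjusted p = 0.591 with an estimated correlation). Adjusted over the list alone, 4 members passed in limma, none of which passed over all genes: Sox18 (log2 1.16, SE 0.26), Ltb (0.69, SE 0.17), Ifitm1 (1.18, SE 0.31) and Gimap1 (0.64, SE 0.17). The sort markers Slamf1, which encodes CD150, and Ly6a, which encodes Sca-1, had 0.43 and 0.49, Kit had -1.18 and Cd48 had -0.14. Without wild-type 3 and 4, Ly6a had -0.13 and Kit 0.15, and without wild-type 1 and 2 Cd48 had 0.12. The call was lost without wild-type 1 (adjusted p = 0.244), wild-type 2 (0.158) or mutant 1 (0.0615), without both wild-type 1 and 2 (0.728), with quantile normalization (0.0992), with library weights (0.163), within the shared title series (0.699) and with the series as a covariate (0.194).

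Itga2b, the platelet integrin CD41 that also marks megakaryocyte-primed stem cells, had 5497 ± 1292 normalized counts in wild-type (n = 4) and 2351 ± 426 in mutant libraries (n = 3), a log2 difference of -1.21 (SE 0.22). It was called by DESeq2 (adjusted p = 7.3e-03) and was lower with limma both with the length slope (adjusted p = 0.0352) and without wild-type 3 and 4 (adjusted p = 0.0411). Those limma fits both set that pair apart and are not separate tests. Plek, the platelet protein pleckstrin, had -1.05 (SE 0.31), Cd63 had 0.63, Vwf -0.45 and Pf4 -0.51. Without wild-type 3 and 4, Plek had -0.97, Cd63 0.19 and Vwf -0.09, and without wild-type 1 and 2 they had -1.14, 1.06 and -0.82. Pf4 varied from 404 to 10550 normalized counts within the wild-type group, and its log2 difference was -2.36 without wild-type 3 and 4 and 1.34 without wild-type 1 and 2. The megakaryocyte and platelet list was not called over all libraries (median -0.11, adjusted p = 0.434; 1 member, Itga2b, passed adjusted over the list alone). It was lower without wild-type 4 (adjusted p = 0.0110) and without wild-type 3 and 4 (0.00698; 0.497 with an estimated correlation). Erythroid markers were not called (median -0.49, adjusted p = 0.0963), but they were lower without wild-type 4 (adjusted p = 1.3e-03), mutant 1 (0.0165) or mutant 3 (1.0e-03), and without wild-type 3 and 4 (0.0009; 0.516 with an estimated correlation).

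Genes of neutrophils and monocytes fell as a list, with 25 of 30 members negative (median log2 -1.85, camera adjusted p = 3.2e-08; adjusted p = 0.718 with an estimated correlation). The call was lost with library weights (adjusted p = 0.242), which gave mutant 1 a weight of 11.2 against 0.42 to 1.05 for the other libraries. Adjusted over the list alone, 12 members passed in limma, against 0 over all genes. Mpo, the granule enzyme myeloperoxidase, had 5257, 4737, 12117 and 6558 normalized counts in wild-type 1 to 4 and 4128, 539 and 801 in mutant 1 to 3 (log2 -2.46, SE 0.66). Ngp and Lcn2, further granule genes, had -2.18 and -2.13, and F13a1, a monocyte gene, had -3.13. F13a1 had 17.5, 23.9, 151 and 102 normalized counts in wild-type 1 to 4 and 2.24, 8.04 and 6.04 in mutant 1 to 3. As a list these genes averaged 0.33 in mutant 1, within the wild-type range of -0.07 to 1.44, against -1.61 and -1.26 in mutant 2 and 3. The mast cell, basophil and eosinophil list fell with 4 of 5 tested members negative (median -1.78, adjusted p = 0.0286; adjusted p = 0.718 with an estimated correlation), and 2 members passed adjusted over the list alone. Hdc, the histamine-forming enzyme, had 146 ± 35.4 and 44.3 ± 22.8 (log2 -1.78, SE 0.36), Ear2 -3.28, Prg2 -2.73 and Cpa3 -0.29. Ear2 had 33.9, 49.9, 15.85 and 11.6 normalized counts in wild-type 1 to 4 and 15.7, 0 and 0 in mutant 1 to 3. Prg2 had 131, 182, 5.01 and 60.7 in wild-type and 19.1, 7.14 and 2.42 in mutant libraries. Both had few counts in the mutant libraries, and their groups overlapped. The log2 difference of Prg2 was -4.24 without wild-type 3 and 4 and -1.22 without wild-type 1 and 2. That call was lost without wild-type 1 (adjusted p = 0.157), wild-type 2 (0.103) or mutant 2 (0.187), without both wild-type 1 and 2 (0.519), with library weights (0.649), within the shared title series (0.572) and with the series as a covariate (0.185).

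Other cell type lists were not called over all libraries. B cell markers had a median of 0.01 but a mean of -0.24 (adjusted p = 0.724), T and NK cell markers 0.31 (adjusted p = 0.428), macrophage and dendritic cell markers -0.10 (adjusted p = 0.724) and stromal and endothelial markers -1.10 (adjusted p = 0.162; 7.5e-03 and lower without mutant 3). Multipotent and lymphoid-primed progenitor markers had -0.06 (adjusted p = 0.724), with 1 member, Ighm (log2 -2.17), passing adjusted over the list alone.

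Cell cycle genes fell as lists. In G2 and M phase 33 of 41 members were negative (median -0.24, camera adjusted p = 5.3e-04; adjusted p = 0.853 with an estimated correlation), and in S phase 29 of 40 (median -0.20, adjusted p = 3.3e-03; adjusted p = 0.853 with an estimated correlation). Mki67, a marker of cycling cells, had 2686 ± 523 (n = 4) and 1603 ± 222 (n = 3) normalized counts (log2 -0.73, SE 0.20). Top2a, Gtse1 and Bub1b of mitosis had -0.61, -0.56 and -0.84, and Blm, Dtl, E2f8 and Ung of DNA replication and repair had -0.70, -0.60, -0.93 and -0.67. Without wild-type 1 or 2 neither list was called (adjusted p = 0.139 and 0.0703 for G2 and M phase, 0.437 and 0.0861 for S phase), and S phase was also lost without mutant 1 (0.141). Without wild-type 3 and 4 the medians were -0.45 and -0.42, and against wild-type 3 and 4 alone the tests pointed upward (adjusted p = 0.748 and 0.607).

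NRF2 targets, which protect against oxidants, rose with 15 of 25 members positive (median 0.24, camera adjusted p = 0.0491; adjusted p = 0.591 with an estimated correlation), and 2 members passed adjusted over the list alone. Gsta4 had 454 ± 82.0 (n = 4) and 870 ± 142 (n = 3) normalized counts (log2 0.94, SE 0.22), and Mgst1, Nqo1 and Fth1 had 0.78, 0.49 and 0.66. The call was lost without wild-type 1 (adjusted p = 0.0720), wild-type 2 (0.151), mutant 1 (0.0546) or mutant 2 (0.130), and 6 of the 17 other camera settings with the preset correlation kept it. Without wild-type 3 and 4 the median was 0.06 (adjusted p = 0.0961), and it was 0.08 with the length slope. Random lists matched on length and expression had a median of 0.15 over all libraries, which put NRF2 targets at percentile 88.6. As for ER chaperones, the exact permutation of the list's mean gave p = 0.0286, with the same limit. For the other lists that camera called, this permutation gave p = 0.0571 (mast cell), 0.143 (neutrophil), 0.171 (ribosomal) and 0.229 (G2 and M phase). It gave 0.343 for oxidative phosphorylation, 0.371 for the proteasome and for S phase, and 0.400 for stem cell markers. The type I interferon response, of interest because pI:pC induces interferon, was not called (42 members, median 0.08, adjusted p = 0.717). Ifit2 had a log2 difference of -0.51, and Xaf1 had 0.68.

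**Figure D3:**
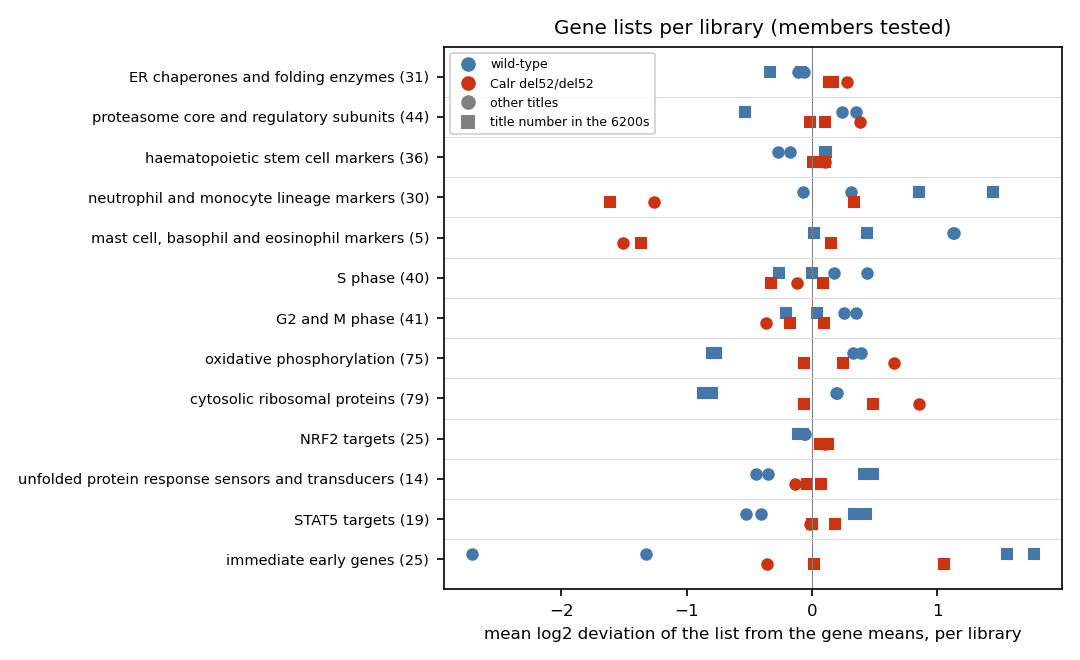
Mean log2 deviation from the gene means of 13 gene lists in each library (members tested in brackets), wild-type in blue above and Calr del52/del52 in red below, squares and circles as in the plot of libraries. ER chaperones and NRF2 targets separate the genotypes, while wild-type 3 and 4 lie at the lower end for ribosomal proteins and oxidative phosphorylation and at the upper end for immediate early genes.

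Among the genes of smallest p, which limma did not pass, Gstm7, a glutathione transferase, had 469 ± 46.7 (n = 4) and 965 ± 63.6 (n = 3) normalized counts (log2 1.04, SE 0.17; DESeq2 adjusted p = 9.3e-05). Bdh2 had 644 ± 70.8 and 1413 ± 276, and Efna1, the RNA gene Snhg12 and Plxna4os1 had log2 differences of 0.94, 1.05 and 1.18. On the other side, Tent5a had 251.0 ± 31.7 and 105 ± 19.1 (log2 -1.26, SE 0.23; DESeq2 adjusted p = 1.75e-03). Slc16a11 had -1.67, the chromatin remodeller Chd7 -0.94 and Olfm4 -4.16, the last with at most 4.46 normalized counts in any mutant library. All of these were called by DESeq2. With the length slope limma called Gstm7, Bdh2, Efna1, Snhg12, Tent5a and Chd7, but without wild-type 3 and 4 it called none of those 6. Their log2 differences in that smaller fit were 0.98, 1.01, 0.88, 0.89, -1.30 and -0.87, so the sizes changed little.

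Transcript models were compared last, to see whether any isoform shifted. Limma called 0 of 30156 transcripts, with 2077 at an unadjusted p under 0.05. The protein-coding transcript of Calr (ENSMUST00000003912.6) had 281 ± 26.9 FPKM (n = 4) and 246 ± 12.3 FPKM (n = 3), a log2 difference of -0.19. The 3 retained-intron models of Calr (ENSMUST00000125998.1, ENSMUST00000128028.1 and ENSMUST00000154774.1) had log2 differences of 0.78, 0.87 and -1.09, none of which passed (limma, adjusted p = 0.661 for each). The smallest p was that of a Dkc1 model marked for nonsense-mediated decay (ENSMUST00000153844.7, log2 2.66, limma adjusted p = 0.0997), named after its values were seen. FPKM of overlapping models are estimates that share reads, and no read count stands behind each value.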

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

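All tests of explanations in this part were chosen after the result was seen, except that the recount of genes over other splits of the libraries was set beforehand. Among 161 values tested for a single wild-type library far from the other 3, 3 (1.86%) passed Dixon's critical value for the gap to the nearest library over the group's range, where chance gives about 5%. The ER chaperone list was one, with wild-type 3 at -0.33 against -0.07, -0.11 and -0.08 (gap over range 0.841), and without wild-type 3 the list was still higher in the mutant (camera, adjusted p = 5.25e-06). Ltb, a stem cell marker, had 3317 normalized counts in wild-type 1 against 3787 to 3833 in the others (0.910). Ung, a DNA repair gene of the S phase list, had 340 in wild-type 1 against 254 to 265 in the others (0.864). Since the wild-type libraries formed pairs, the widest gap of a value can lie between the pairs. The check can then miss an outlying library, so the low share does not show that few stood apart.

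The wild-type libraries formed 2 pairs, with 8810 genes differing between them in limma. Gene length is a candidate for part of the cause, since the difference followed exonic length (Spearman's rho 0.509 across genes, which are not independent). A smooth trend with length was not the whole cause, because 7785 genes still differed after it was removed. That trend explained 21.9% of the variance of the difference, and a length effect that varies between genes around it was not tested. Thinning all libraries to 1 depth left 8621, which argues against sequencing depth. The title series alone did not sort the libraries in the same way, although mutant 1 and 2 share the series of wild-type 3 and 4. Mutant 1 and 2 had r of 0.936 and 0.954 with wild-type 3, against 0.967 and 0.966 with wild-type 1. With wild-type 4 they had 0.937 and 0.959, against 0.971 and 0.967 with wild-type 2. Handling of the wild-type libraries stays open, and no biological explanation was tested, since the labels give no difference within the wild-type group.

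ER chaperones and folding enzymes were higher in the mutant libraries. The tests argue against length bias (adjusted p = 2.99e-07 with the length slope) and against wild-type 3 and 4 (adjusted p = 3.35e-06 without them) as the whole cause, but the median went from 0.41 to 0.26 and 0.25, so either may hold part of it. Since the slope was highest in wild-type 3 and 4, these tests overlap and cannot tell length bias from that pair. Of the 35 splits, 1, the real one, gave a difference of the list's mean as large (0.35, highest other 0.31), as it also did for NRF2 targets. This share is the floor of the test, which was added after the result was seen. Adjusted over the 36 lists, the exact permutation gave p = 0.514 for both lists, so chance was not excluded. With a correlation estimated per list the adjusted p of the ER chaperone list was 0.591, 0.340 with the length slope and 0.329 without wild-type 3 and 4, so shared variation between its genes stays open. A higher chaperone level in Calr del52/del52 stem cells may underlie it, as a hypothesis that other libraries would have to test, and a batch among the libraries was not excluded.

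Proteasome, oxidative phosphorylation and ribosomal protein genes were higher in the mutant over all libraries. Random lists matched on length and expression had medians of 0.21, 0.39 and 0.38, against 0.33, 0.55 and 0.76 for the lists (percentiles 98.6, 100 and 100), which was first taken as the test of length bias and then replaced by the length slope, because members of a list move together and random genes do not. The proteasome and oxidative phosphorylation lists turned lower in the mutant with the length slope (adjusted p = 0.000726 and 0.0429; 0.609 and 0.823 with an estimated correlation) and without wild-type 3 and 4 (0.000679 and 0.0456; 0.782 and 0.905), so length bias and that pair both remain as explanations of their rise, though with slope and series together oxidative phosphorylation was higher (0.00022) and the proteasome was not called (0.969). The ribosomal list stayed higher in these overlapping fits at the preset correlation (camera, adjusted p = 2.29e-14 and 1.06e-05). Its median went from 0.76 to 0.22 and 0.23. Its members moved together, with an estimated correlation of 0.987 over all libraries. These fits therefore cannot tell whether length bias or that pair was the whole cause of its rise. The list averaged 0.20 and 0.19 in wild-type 1 and 2 and 0.49, -0.06 and 0.85 in mutant 1 to 3, so these groups overlapped. With an estimated correlation its adjusted p was 0.450 and 0.825, so whether genotype played a part stays open.

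Recounts over the 35 splits of the 7 libraries into 4 and 3 bear on the counts of calls. For genes over all libraries the real count was 0 in limma (1365 unadjusted), so all 35 splits gave as many, and the highest other, 5690 with wild-type 3, wild-type 4 and mutant 2 as the group of 3, points to a structure of the samples. With the length slope, the real count of 126 was matched by no other split (1 of 35, the smallest share possible, highest other 40). That fit was chosen after seeing the split within the wild-type group, and it called 0 genes (1071 unadjusted) once the title series was added. The share holds only for the fit as chosen and does not exclude chance. For lists, 18 of 35 splits gave at least the real count of 10 (highest other 17), so chance could not be excluded. For transcripts the real count was 0 (2077 unadjusted), all 35 splits gave as many, and the highest other was 7842.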

How the results depend on the processing

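Alternatives without wild-type 3 and 4, without wild-type 1 and 2 or only outside the shared title series, with the length slope or the title series as covariates, and the list test with TMM were chosen after seeing the data; all others were set beforehand. The count of 0 genes in limma (1365 unadjusted) held under each change of pseudocount, filter, scaling, weights or variance model, with FPKM summed per gene, without chromosomes X and Y and with any 1 library left out, and in edgeR (1637 unadjusted). The unadjusted count was 6068 with library weights and 613 to 2407 with 1 library left out. Those weights were 11.2 for mutant 1 and 0.42 to 1.05 for the other libraries. DESeq2 called 84 (34 higher, 50 lower), of which 27 were also called with the length slope and 5 without wild-type 3 and 4. Limma called 6010 (2631 higher, 3379 lower) within the shared title series, 1022 (554 and 468) outside it, 6828 (3165 and 3663) without wild-type 1 and 2, 51 (38 and 13) without wild-type 3 and 4, 126 (98 and 28) with the length slope, 3597 (1599 and 1998) with the title series and 0 with slope and series together (1071 unadjusted). EdgeR called 90 (69 and 21) with the slope and 22 (16 and 6) without wild-type 3 and 4. The difference between the wild-type pairs enters the spread of the full comparison and the effect of the smaller ones by construction; other causes were not tested. Of 36 lists, 10 were called; the number was 0 with an estimated correlation or by fry (smallest adjusted p 0.0653), 5 without wild-type 1 or 2 and at most 14 with any other library left out, 19 without wild-type 3 and 4, 20 with the slope, 6 with the series, 23 with both, and 0 with the slope or without wild-type 3 and 4 when the correlation was estimated. Over the 17 camera settings with the preset correlation, ER chaperones and ribosomal proteins kept their call in 17, neutrophil genes in 16 (lost with library weights), oxidative phosphorylation in 15, G2 and M phase in 13, the proteasome in 12, S phase in 11, mast cell genes in 10, stem cell markers in 9 and NRF2 targets in 6. With TMM the same 10 lists were called. Lists that turned were the proteasome (lower without wild-type 3 and 4, adjusted p = 0.000679; with the slope 0.000726; with an estimated correlation 0.782 and 0.609), oxidative phosphorylation (lower, 0.0456 and 0.0429; estimated 0.905 and 0.823), immunoproteasome (lower, 0.0069 and 0.00157) and p53 targets (higher, 0.00838 and 0.00586, and 0.00443 with slope and series). With slope and series, the interferon response (0.00127) and cholesterol synthesis (0.000325) were lower. Within the shared series and without wild-type 1 and 2, S phase (0.486 and 0.607) and G2 and M phase (0.400 and 0.748) pointed upward and immediate early genes were lower (1.97e-05 and 1.48e-05); the cause was not tested. Under the same settings log2 differences turned, with a limma adjusted p under 0.05, for Egr3 (-2.27 and -2.51), Egr4 (-1.40 and -2.07), Klf2 (-1.27 and -1.53), Klf4 (-1.58 and -1.75), Rhob (-1.45 and -1.73) and Ern1 (-1.02 and -0.97). Other genes, such as Fos, Hes1, Id1, Dusp1, Hspa1a and Gdf15, changed sign without wild-type 1 and 2 but did not pass there. Transcripts went from 0 (2077 unadjusted) to 3 (3 higher, 0 lower) with no filter, 1 (0 higher, 1 lower) without mutant 2, and 2 (1 higher, 1 lower) both without wild-type 3 and 4 and with the slope; with any other library left out the count was 0. The log2 difference of Calr was -0.13 from summed FPKM, past its exact test, and between -0.10 and -0.18 with any 1 library left out. No paired analysis was possible because the titles of the groups share no numbers. Depth was 21325340 reads or more per library. On simulated reads at these depths, carrying the split of the wild-type pairs lowered limma's share of 2-fold changes called from 100% to 8%. Those reads had the same preset spread for every gene, so whether the split alone explains why limma called no real gene was not tested.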

Other observations

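All fits that leave out a wild-type pair or use the length slope in this part were chosen after the result was seen, and the genes outside the fixed lists were named after their values were seen. Immediate early genes, which cells switch on within minutes of a stimulus, differed widely between the wild-type pairs. Fos had 4007 and 15386 normalized counts in wild-type 1 and 2, 135480 and 147158 in wild-type 3 and 4, and 56786, 134259 and 58041 in mutant 1 to 3. Of 25 members, 24 were higher in the mutant than in wild-type 1 and 2 (median log2 1.99, camera adjusted p = 2.5e-28, 5 genes called), and 24 were lower than in wild-type 3 and 4 (median -1.19, adjusted p = 1.5e-05, 15 genes called). Over all 7 libraries the list was not called (median 0.33, adjusted p = 0.398), but it was higher without wild-type 3 (adjusted p = 1.1e-03) or wild-type 4 (3.5e-04). No list passed with an estimated correlation in the fit of all libraries (adjusted p = 0.853 for this list) or without wild-type 3 and 4. Klf2, Klf4, Hes1 and Dusp1 had means in the same order, as did the inducible heat shock genes Hspa1a (1 and 7, 5186 and 3650, and 2124, 8055 and 86 normalized counts) and Hspa1b and the stress cytokine Gdf15. NF-kB and TNF response genes were not called over all libraries (median 0.08 but mean -0.07, adjusted p = 0.717) and were higher without wild-type 3 and 4 (adjusted p = 8.5e-05; 0.403 with an estimated correlation).

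Of the 29 genes that limma called both with the length slope and without wild-type 3 and 4, 28 had a symbol (22 higher, 6 lower). Itga2b was among the 6 lower genes, with Ache, which encodes acetylcholinesterase, the sphingosine-1-phosphate exporter Mfsd2b, Serpine2, Slc22a3 and Tuba8. Without wild-type 1 and 2, Tuba8 had a log2 difference of 0.45 and Serpine2 -0.10. Itga2b, Ache, Mfsd2b and Slc22a3 stayed lower there (-1.275, -0.73, -0.95 and -0.69). Ache had 385 ± 157 (n = 4) and 154 ± 3.97 (n = 3) normalized counts (log2 -1.23 over all libraries; limma adjusted p = 9.6e-03 with the slope and 0.0199 without wild-type 3 and 4). Myl10, a myosin light chain gene, had 2978 ± 2346 and 18711 ± 9457 (log2 2.89 over all libraries; 3.53 with the slope and 3.92 without wild-type 3 and 4). Plscr2, Lrrc70, Adam5, Dhrs3 and the G protein regulator Rgs2 were also higher in both fits, with every mutant library above every wild-type library. Fos, Klf2, Klf4, Egr3, Egr4, Hes1, Id1 and Rhob were called higher in both fits, yet each had a negative log2 difference without wild-type 1 and 2. Tgfbr3, a TGF-beta co-receptor, had 1967 ± 755 and 661 ± 119 (log2 -1.50; DESeq2 adjusted p = 7.6e-03; limma adjusted p = 5.5e-03 with the slope and 0.0890 without wild-type 3 and 4).

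Further fixed lists were not called over all libraries. Autophagy and lysosome genes had a median of 0.12 (adjusted p = 0.120), MYC targets in ribosome biogenesis 0.02 but a mean of -0.11 (adjusted p = 0.482), cholesterol synthesis 0.21 (adjusted p = 0.324; higher without mutant 3 with 3.5e-06 and within the shared title series with 0.00157), glycolysis and hypoxia 0.04 (adjusted p = 0.759), p53 targets -0.08 (adjusted p = 0.746) and apoptosis regulators -0.08 (adjusted p = 0.717). Autophagy and lysosome genes were higher without wild-type 3 (adjusted p = 0.0343), wild-type 4 (0.0430) or mutant 3 (0.0462). MYC targets were lower without wild-type 4 (adjusted p = 0.0498) and without wild-type 3 and 4 (4.2e-08; 0.403 with an estimated correlation). In the last setting autophagy and lysosome genes (3.18e-04; 0.329 with an estimated correlation) and p53 targets (0.00838; 0.552) were higher.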
